A study of Urocitellus parryii with 44 samples.

How the data were processed

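Brown adipose tissue RNA of 8 arctic ground squirrels was measured on 4 mouse cDNA membranes, and the labels place 3 animals in the summer active group and 5 in the winter torpor group. The series has 44 columns, 20 of summer and 24 of torpid animals, since 3 RNAs were split before measurement. The authors deposited linear spot intensity values, already divided by the median of each column: the column median is 1 on every membrane when empty cells are ranked lowest. Image analysis, background treatment and the reason for empty cells are not given in the sources used here. Empty cells made up 3.45% of the values and lay among the dimmest probes, with a median signal percentile from 2.19 on MA07 to 8.22 on MA10. Scanner files were not used here, so no signal over background could be set.

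Values were taken to log2 as deposited, with empty cells as missing and no floor, because the columns were already scaled to a common median. Duplicates of a split RNA were averaged on the log2 scale, so that n is 3 and 5 animals. Each membrane was fitted alone with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with the default prior, torpor minus summer, two-sided), for probes with values in at least 2 animals of each group. Benjamini-Hochberg adjustment was made over the tested probes of all 4 membranes, with a threshold of 0.05. Spots that share a clone were kept as separate probes. A further 552 probes had too few values to test, of which 2 were empty in all summer and no torpid animals and 6 in all torpid and no summer animals.

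Gene symbols came from the platform annotation supplied with the files, which can be old: 25070 probes had 1 symbol, 941 several and 12389 none, and probes with several symbols were left unnamed in the text. The probes are mouse sequences and the RNA is of squirrel, so a symbol names the mouse gene. Of 11626 symbols counted without regard to case, 84.2% match a gene symbol or synonym in the RefSeq annotation of the squirrel. The 11786 genes given below count spellings that differ only in case as separate. No genome build is named in the sources used here and no coordinates are given.

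The 23 gene lists, the rule for named genes and the tests of the comparison between torpor and summer were fixed before the data were examined. Several tests of technical explanations, and 5 alternatives, were chosen later. A gene with several probes was represented in its list by the probe with the highest signal percentile on its membrane. Lists were tested with cameraPR on the moderated statistics (preset correlation 0.01), with camera at an estimated correlation, and with fry, which asks whether a list moves in 1 direction without comparing it with other genes, and adjusted over the 23 lists. Lists defined by symbol patterns hold a few related genes, such as Eef2k among translation factors and Cox10 in the respiratory chain. The lists were thermogenic genes, fatty acid oxidation, triacylglycerol storage, fatty acid synthesis, cholesterol synthesis, glycolysis, the tricarboxylic acid cycle, the respiratory chain, ribosomal proteins, translation factors, chaperones, the proteasome, extracellular matrix, cold-inducible RNA-binding proteins, antioxidants, cell division, the circadian clock, and markers of muscle, blood, immune, endothelial, white fat and nerve cells. Named genes were the 12 called genes with the largest rise and the 12 with the largest fall among those with complete separation of the groups (11 fell), up to 4 genes per list with the smallest p, and a fixed set of genes of brown fat and controls.

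The fit was tested on simulated data drawn from the real probes' means and spreads. For the comparison of torpor with summer over 37848 probes, 66% of 200 probes changed by 2 on the log2 scale were recovered when each group had its own spread, and 87.5% of those changed by 3, with 10 and 22 false calls. With a single spread, 130 and 191 of the 200 were recovered, with 6 and 8 false calls. With a spread per group, 132 and 175 were recovered beside the 10 and 22 false calls. The false share of calls was then above what the adjusted p threshold allows, and below it with a single spread. None of the 200 changed by 1 were recovered. In 5 runs with no change, 0 probes were called, with either a single spread or a spread per group. Runs without changed probes do not show how many calls are false when some probes change. In a simulation that shifted the ribosomal list by 0.5, that list passed and none of the other 22 did. The simulated probes were independent of each other, whereas the real ribosomal list had an estimated correlation of 0.35. This simulation therefore does not show how the list test behaves with correlated members.

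Alternatives covered the scaling between columns, a floor at the 10th percentile, filters on dim probes, the variance model, animal weights, the adjustment and its threshold, the use of technical duplicates, a replicate block, each animal left out, and the probe and correlation used for lists. A further 5 were added after the data were examined: a variance per group, averaging of spots with the same clone, leaving out probes beside a brighter probe, leaving out the brightest probes of MA11, and leaving out MA10. Here beside means 5 index positions from a probe at least 4-fold brighter, on any membrane, which took out 7926 probes. Whether such probes are neighbours on the membrane is not known. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.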

Results

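Brown adipose tissue, the fat that mammals burn to make heat, was compared between arctic ground squirrels in winter torpor and active squirrels taken in August. Torpor is the hibernator's state of greatly lowered metabolism and body temperature. The data came from 5 torpid and 3 summer animals. Each animal's total RNA, labelled with radioactive phosphorus, was hybridised to 4 membranes of mouse cDNA probes named MA07, MA08, MA10 and MA11, with 9600 probes on each and 11 columns per membrane. The RNA of summer animals 1 and 2 and of torpid animal 5 was split and measured in duplicate, and each pair was averaged to 1 animal. Season and activity state changed together, so the comparison asks which transcripts differ between winter torpor and summer activity without separating these 2 factors. Of the 38400 probes, 37848 could be tested, and 25070 carried a single gene symbol, for 11786 genes. The number of arrays limits the precision, with a median standard error of 0.29 on the log2 scale.

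Sucla2, Dld, Cycs and Acadm were among the genes most strongly raised in torpor. Sucla2, the ADP-forming subunit of succinyl-CoA ligase in the tricarboxylic acid cycle, was 20.5-fold higher on MA11 (probe 7209), at 3.94 ± 0.24 (SD, n = 5) in torpor against -0.41 ± 0.92 (SD, n = 3) in summer on the log2 scale of intensity over the column median. Dld, the dihydrolipoamide dehydrogenase shared by the pyruvate and 2-oxoglutarate dehydrogenase complexes, rose by 3.33 on the log2 scale, and Cycs (cytochrome c) was 9.56-fold higher and Acadm (medium-chain acyl-CoA dehydrogenase) 7.11-fold higher. Of the 11 genes that fell, 8 encode parts of the translation machinery, all by MA10 probes: Eef1g, a subunit of translation elongation factor 1, was 7.43-fold lower, and the ribosomal protein genes Rpl36 and Rpl35 were 7.13- and 5.21-fold lower. Patl1, an mRNA decay factor, ranked between these at 5.77-fold lower.

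By limma, 117 probes passed an adjusted p of 0.05, of which 98 were higher and 19 lower in torpor. The 83 of these with a single symbol covered 67 genes, 56 higher and 11 lower. At an unadjusted p under 0.05 there were 4379 probes, 2420 higher and 1959 lower. In all 117 probes every torpid animal lay on the same side of every summer animal, as did 8.50% of all tested probes, where chance gives 3.57%. The smallest called difference was 1.13 and the median called difference 2.20 on the log2 scale, and no simulated change of 1 was recovered. In simulated data with a spread per group, false calls exceeded the share that the threshold allows. A fit with a variance per group called 81 probes, all among the 117. The count and the called probes moved with the animals. It was 347, 104 and 162 without summer animal 1, 2 or 3, and only 95, 44 and 64 of these probes were among the 117. The count was 45, 17, 50 and 60 without torpid animal 1, 2, 3 or 4, with 45, 17, 48 and 56 among the 117. Without summer animal 3 only 6 probes were lower. Cyclic loess between columns gave 63 probes, 46 higher and 17 lower, so that 73.0% were higher in place of 83.8%.

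Sucla2 rose on all 4 membranes, by 4.24 ± 0.37 (SE) on MA07, 4.30 ± 0.46 on MA08, 3.96 ± 0.64 on MA10 and 4.36 ± 0.35 on MA11, with adjusted p from 0.0010 to 0.015; the MA10 and MA11 probes are of the same clone. Its other 2 probes did not pass, at 1.40 on MA07 and -0.68 on MA10. Cycs passed with 4 of its 5 probes, and all 5 lay between 1.90 and 3.26. Its called probes at 1.90 on MA08 and 2.27 on MA11 are of the same clone. Acadm passed with 2 of 3 probes, and its lowest value was 2.28. Dld passed with 2 of 3 probes, which share a clone, and all 3 lay between 2.90 and 3.33.

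Other genes with the largest rises were Anapc7 (3.13 ± 0.39, a subunit of the anaphase-promoting complex), Ghitm (2.85 ± 0.46, a protein of the inner mitochondrial membrane), Laptm4a (2.80 ± 0.40, a lysosomal membrane protein) and Fndc3a (2.77 ± 0.43). Taf1d, Sltm, Ptp4a1 (a protein tyrosine phosphatase) and Mat2b (the regulatory subunit of methionine adenosyltransferase) followed, at 2.75, 2.71, 2.69 and 2.65. Of the 8 fits that each left out 1 animal, Anapc7, Laptm4a and Sltm passed in 7, Taf1d in 4, Fndc3a in 3, Ghitm and Ptp4a1 in 2 and Mat2b in 1. Mat2b gave 4.02 with the first duplicates (adjusted p = 0.055) and 1.28 with the second (adjusted p = 0.31). The rise rested on 1 of 6 probes for Sltm, 1 of 5 for Taf1d, 1 of 3 for Anapc7 and 1 of 3 for Mat2b, and the second largest values of these genes were 0.77, 0.43, 0.43 and 0.37. Their lowest values were -0.61, -0.56, 0.22 and -1.07. Ghitm passed with 1 of 6 probes and Laptm4a with 1 of 3, and all probes of both were positive, from 0.80 and 0.97 upwards. For Ptp4a1, 3 of 5 probes passed, and all 5 were positive, from 0.33 upwards. The Fndc3a probe lies 5 index positions from a Cycs probe on MA07 (2.77 against 3.24), and its other probe, on MA10, gave 0.97 (adjusted p = 0.44 by limma).

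Among the reduced genes, Eef1g fell with 4 of its 8 probes, the largest change being -2.89 ± 0.40, and 3 of these 4 lie 10 index positions apart on MA10 (-2.83, -2.89 and -2.78). Another of its probes had a positive value, 0.07, and its brightest probes on membranes other than MA10 averaged -0.56. Rpl36 (-2.83 ± 0.52), Rpl35 (-2.38 ± 0.43), Rps15 (-2.30 ± 0.41), Rps10 (-2.29 ± 0.36), Rpsa (-2.23 ± 0.42), Rpl3 (-2.06 ± 0.42) and Rplp1 (-1.95 ± 0.39) each fell with 1 probe, and no probe of these 7 genes had a positive value. With 1 animal left out in turn, Rps10 passed in 8 of 8 fits, Rpl35 and Rpsa in 3, Rps15 in 2, Rpl36 and Rplp1 in 1 and Rpl3 in 0. The rest were Patl1 (-2.53 ± 0.43), Stx6 (-2.30 ± 0.47, a SNARE protein of the trans-Golgi network) and Zbtb44 (-2.23 ± 0.38, a zinc finger protein). Patl1 and Stx6 fell with 1 probe each, and each also had a probe with a positive value, 0.70 and 0.15. With 1 animal left out Patl1 passed in 5 of 8 fits, and Stx6 and Zbtb44 in 2. The single Zbtb44 probe was among the dimmest of MA08 (signal percentile 0.28), had values in 4 of the 5 torpid animals, and gave -0.24 with a floor at the 10th percentile.

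**Figure D1:**
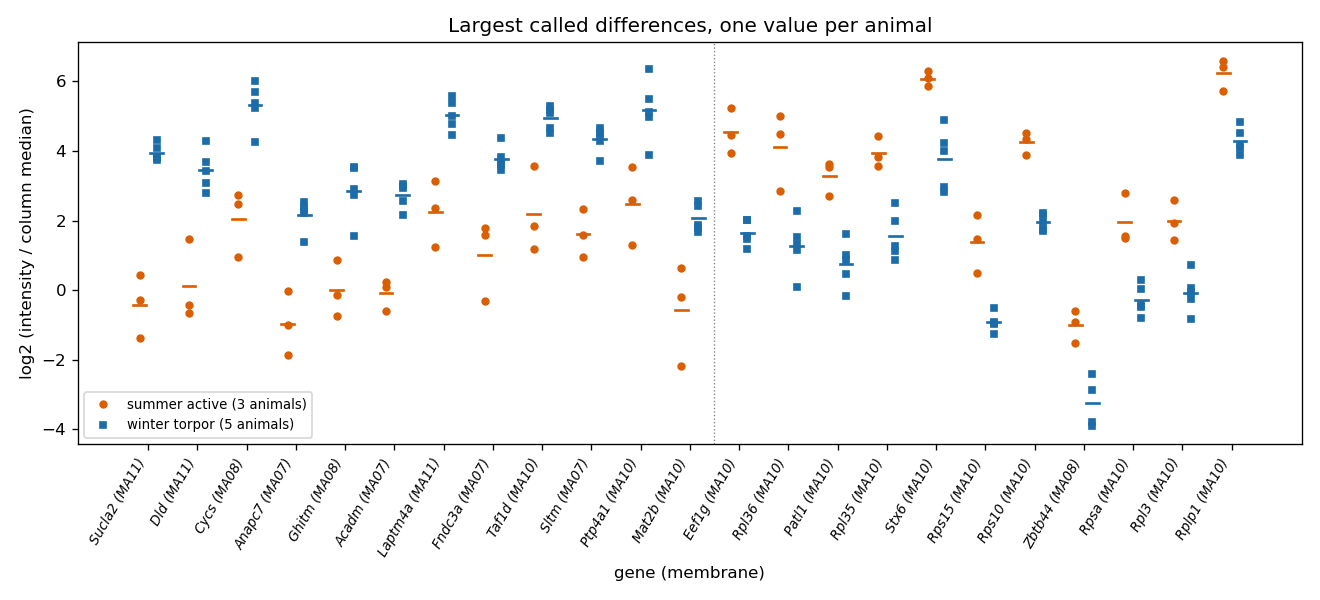
Log2 intensity over the column median for each of the 3 summer animals (orange circles) and 5 torpid animals (blue squares; 4 for Zbtb44, which has no value in torpid animal 2), with group means as bars, for the 12 genes with the largest rises (left of the dotted line) and the 11 genes that fell. Each measured torpid animal lies beyond every summer animal, for Sucla2 at a mean of 3.94 against -0.41.

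Fatty acid uptake and oxidation genes rose as a list in torpor. Of 31 measured members 24 had positive values, the median was 0.42, and camera gave an adjusted p of 8.2e-06 with the preset correlation. This call was lost, at an adjusted p = 0.099 with an estimated correlation. Another question, whether the list moved on balance in 1 direction without comparison to other genes, was tested with fry (adjusted p = 0.011). Acadm passed the threshold over all probes, and 7 members passed when adjusted over the list alone: Acadm, Acadl (2.31 ± 0.42), Acaa2 (1.79 ± 0.37), Fabp3 (1.99 ± 0.50), Etfdh (1.57 ± 0.46), Decr1 (1.59 ± 0.44) and Hadh (0.94 ± 0.28). These encode enzymes of mitochondrial β-oxidation and its electron transfer, and the fatty acid binding protein of heart. The 4 Acadl probes ran from 0.15 to 2.31, with a median of 0.45. A probe of Slc25a20, another member, also passed over all probes (1.73 on MA11) but did not represent that gene in the list. With each gene represented by its probe of median fold change, the list median was 0.07 (adjusted p = 0.077).

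The tricarboxylic acid cycle list rose too, with 15 of 18 members positive and a median of 0.41 (camera adjusted p = 4.0e-06). That call was lost, at an adjusted p = 0.34 with an estimated correlation, and fry gave 0.14. Dld (3.11 ± 0.45) and Dlst (2.30 ± 0.35) passed over all probes, and Idh3a (2.18 ± 0.37; another Idh3a probe, at 1.68, passed over all probes), Mdh1 (1.51 ± 0.29) and Sucla2 joined them among the 5 adjusted over the list alone. In this list Sucla2 is represented by its brightest probe, at 1.40. Dlst passed with 1 of 5 probes, the lowest at -0.09, and its call was lost without summer animal 2 (adjusted p = 0.052) or 3 (0.054), without torpid animals 1 to 4 in turn (0.062 to 0.081) and with cyclic loess (0.091). The call of this Dld probe was likewise lost without torpid animals 1 to 4 in turn (0.056 to 0.075) and, narrowly, without summer animal 2. The respiratory chain and ATP synthase list rose with 66 of 85 members positive and a median of 0.30 (camera adjusted p = 1.9e-05). It too was lost, at an adjusted p = 0.43 with an estimated correlation, and fry gave 0.20. Cycs (3.24 ± 0.41) and Cox6c (2.01 ± 0.28) passed over all probes, and 10 members adjusted over the list alone, among them Atp5b (4.08 ± 0.82), Atp5a1 (2.92 ± 0.58), Uqcrb (2.78 ± 0.58) and Ndufa8 (1.75 ± 0.35). The other Atp5b probes ran from 0.55 to 2.29, and the probe at 2.29, on MA11, passed over all probes. Those of Atp5a1 gave 2.50 and 2.79. Leaving out summer animal 2 gave 2.91 for the Atp5b probe of the list and 1.95 for that of Atp5a1. A camera p as small arose in 3 of the 56 divisions of the 8 animals into 3 and 5 for the cycle and in 11 for the chain.

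Glycolysis and glucose uptake genes had 14 of 20 positive values and a median of 0.33 (camera adjusted p = 0.014), with 0 members past the threshold over all probes. The list call was lost, at an adjusted p = 0.34 with an estimated correlation. By fry, which makes no comparison with other genes, the adjusted p was 0.039. Adjusted over the list alone, 5 rose (Pgk1, Ldha, Ldhb, Gapdh and Pdhb) and 2 fell (Aldoa, -2.08 ± 0.58, and Eno3, -2.19 ± 0.68), so that the members that passed went both ways. Ldhb, the heart-type lactate dehydrogenase subunit, gave 2.06 ± 0.56. The list's adjusted p was 0.12 and 0.42 without summer animal 1 or 2.

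Ribosomal protein genes fell as a list, with 53 of 75 members negative and a median of -0.29 (camera adjusted p = 1.2e-05). The call was lost, at an adjusted p = 0.58 with an estimated correlation, and fry gave 0.38. Rplp1 passed over all probes, and 6 members adjusted over the list alone (Rplp1, Rpl36, Rpl3, Rpsa, Rpl31 and Rpl10), all represented by MA10 probes. The called probes of Rpl36, Rpl35, Rps15, Rps10, Rpsa and Rpl3 did not represent these genes in the list. The median of all ribosomal probes was -0.85 on MA10 against -0.15, -0.05 and -0.22 on MA07, MA08 and MA11. Without summer animal 3 the median was 0.04 (adjusted p = 0.84). Of the 56 divisions of the animals, 23 gave a camera p as small.

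White adipocyte markers also fell as a list, with 7 of 8 negative and a median of -0.22 (camera adjusted p = 0.012). Adjusted p = 0.34 with an estimated correlation, so that the call was lost, and fry gave 0.066. No member passed over all probes, and 2 passed adjusted over the list alone, Agt (angiotensinogen, -1.996 ± 0.42) and Psat1 (a serine synthesis enzyme, -1.58 ± 0.43). The other probes of Agt gave -0.28 and 0.01, and those of Psat1 -0.15 and 0.11. The adjusted p was 0.11 without summer animal 3. Without MA10, which holds both of these probes, the median was -0.12 (adjusted p = 0.48).

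**Figure D2:**
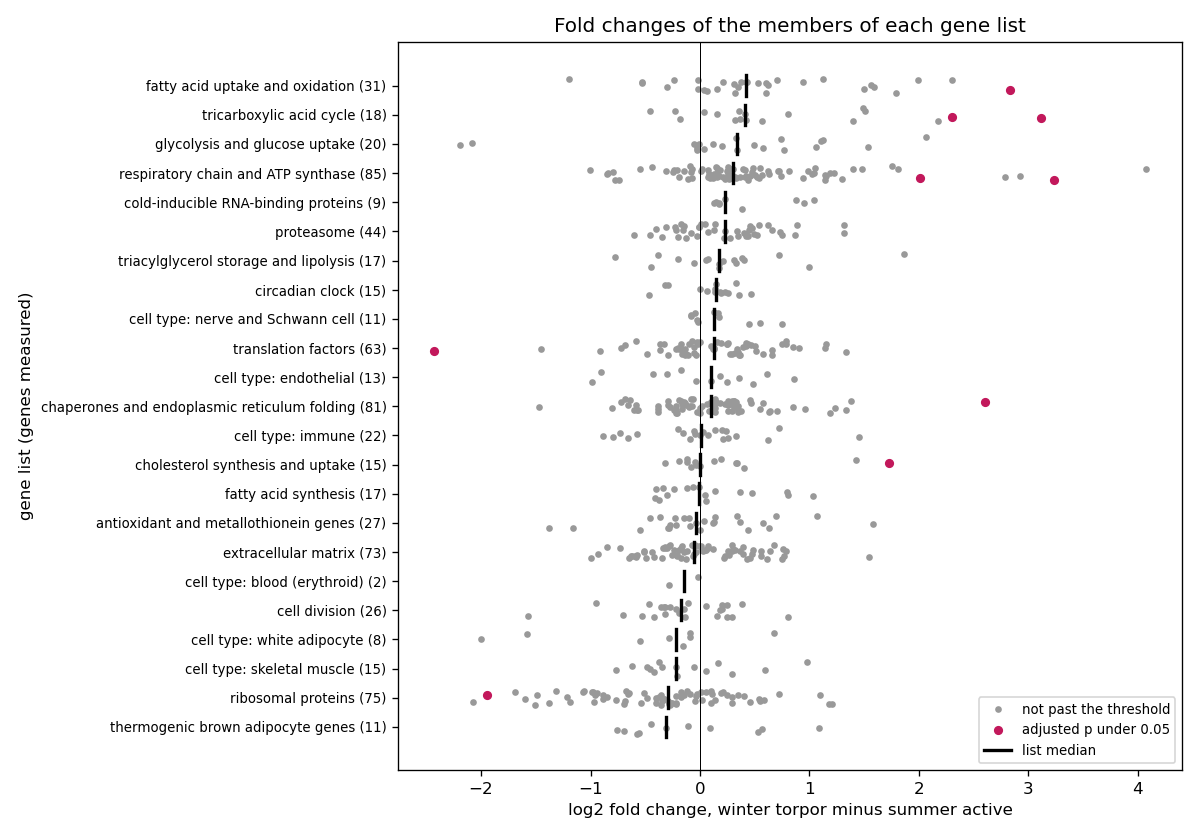
Log2 fold change, winter torpor minus summer active, of each measured gene (1 probe per gene) in the 23 gene lists, with list medians as black bars, genes past an adjusted p of 0.05 in red and the other genes in grey. Medians run from -0.31 for thermogenic genes to 0.42 for fatty acid oxidation, and 9 points are red.

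The thermogenic brown adipocyte list did not pass, with a median of -0.31 over 11 genes (camera adjusted p = 0.53). Esrrg, an oestrogen-related receptor, passed adjusted over the list alone (1.09 ± 0.29), and its 3 probes ran from -0.03 to 1.09 with a median of 0.27. Bmp8b, Dio2 and Ppargc1a had values of -0.44, -0.58 and -0.76. The triacylglycerol storage and lipolysis list gave an adjusted p of 0.49, and Dgat2, which makes triacylglycerol, passed over the list alone (1.86 ± 0.37). Pck1, Lipe and Dgat1 stood at 1.0, -0.78 and -0.39. Cholesterol synthesis (adjusted p = 0.53) held 1 called gene, Insig1 (1.73 ± 0.31), an inhibitor of sterol synthesis, beside Fdft1 at 1.43. The Insig1 call (adjusted p = 0.0495) was lost whichever animal was left out, with adjusted p from 0.053 without summer animal 1 to 0.11 without torpid animal 1, and with quantile normalization (0.055) or cyclic loess (0.083). Fatty acid synthesis gave an adjusted p of 0.99, and its members with the lowest p, Acacb, Pgd, Fasn and Fads1, had values of 0.79, 0.80, -0.41 and 1.03.

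Translation factors (adjusted p = 0.72) held 1 called gene by the probes that represent the list, Eef1g, beside Eif4e (1.15), Eef1d (-1.45) and Eif1b (0.58). A probe of Eif2b2 on MA08 that did not represent its gene also passed over all probes, and it rose (1.25, limma adjusted p = 0.045). Chaperones (adjusted p = 0.78) also held 1, the mitochondrial Hsp70 gene Hspa9 (2.61 ± 0.36; 3 of its 7 probes passed and 2 were negative), beside Hsp90aa1 (-1.47), Dnajc11 (-0.59) and Pdia4 (0.96). The proteasome list had a median of 0.23 (adjusted p = 0.051), with Psmd14 past the threshold over the list alone (1.32 ± 0.29). The antioxidant list (adjusted p = 0.94) held Sod2, the mitochondrial superoxide dismutase, past it over the list alone (1.58 ± 0.32). For cell division the median was -0.17 (adjusted p = 0.055), with Mki67, Rrm2 and Mcm2 at -0.95, -1.57 and -0.47 and Bub1, from a very bright group of MA11 probes that were lower as a whole, at -0.71. All 9 cold-inducible RNA-binding protein genes had positive values (median 0.23, adjusted p = 0.20), including Hnrnpdl (1.04) and Srsf2 (0.96). The median was 0.94 and 0.46 without summer animal 1 or 3, where the list passed (adjusted p = 0.015 for both), and 0.025 without summer animal 2 (adjusted p = 0.80), when Srsf2 gave 0.025. The circadian clock list (adjusted p = 0.83) held Tef at 0.46 and Nr1d1 at -0.32, and extracellular matrix (adjusted p = 0.42) held Thbs1 at -0.85, Mmp14 at -0.73 and Col1a2 at 0.78 (median of its 7 probes 0.03). No member of these 4 lists passed over all probes or adjusted over the list alone.

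Markers of other cell types did not pass as lists: adjusted p = 0.35 for skeletal muscle (median -0.22 over 15 genes), 0.62 for nerve and Schwann cells (0.13 over 11), 0.78 for immune cells (0.01 over 22), 0.91 for endothelium (0.11 over 13) and 0.78 for erythroid cells (-0.15 over 2), where cyclic loess gave negative medians for nerve, immune cells and endothelium. None of their members passed over all probes or adjusted over the list alone. Immune markers had Lcp1 at 1.45, H2-Eb1 at -0.80 and Cd74 at -0.66, endothelial markers had Vwf at -0.99 and Cldn5 at 0.61, and muscle markers had Actn3 at 0.97 and Tnnt1 at -0.62. The nerve markers Nefm and Gfap stood at 0.75 and 0.45, and Alas2 and Hbb-b1 at -0.28 and -0.01. Some of these genes had other probes of opposite sign: the 5 Lcp1 probes had a median of -0.29, and the lowest values of Actn3 and Nefm were -0.53 and -0.52. The median, mean and test differed in sign for the fatty acid synthesis, antioxidant, immune and endothelial lists, whose medians were -0.0053, -0.03, 0.01 and 0.11 and means 0.09, 0.02, 0.0042 and 0.0018, with the test pointing down in each.

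Several genes of brown fat had been fixed for reporting whatever their values, and none of those measured passed over all probes. Fabp3 gave 1.99 ± 0.50 on MA07 (limma adjusted p = 0.17) and 0.28 on MA10. Lpl, lipoprotein lipase, stood at 0.77 and 0.37 on MA10, and Pdk4, a pyruvate dehydrogenase kinase, at -0.30. The 3 Fasn probes gave -0.41, -0.11 and -1.19, and the 3 Scd1 probes -0.26, 0.14 and 0.56. Cirbp and Rbm3, cold-induced RNA-binding proteins, stood at 0.22 and 0.88 for Cirbp and 0.38 for Rbm3. Gapdh gave 1.12 (adjusted p = 0.26), and the 13 Actb probes ran from -1.18 to 1.68, with 4 of them changing sign under cyclic loess, so neither served as a fixed reference. No probe carried Ucp1, Fabp4 or Adipoq as its single symbol.

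The called probes were spread unevenly over the membranes. MA07 held 20, all higher, and MA08 held 31 higher and 2 lower. MA11 held 25 higher and 1 lower, and MA10 held 22 higher and 16 lower, including 7 ribosomal protein probes and the 4 Eef1g probes. The difference in the share of lower calls between membranes was not tested. Without MA10 the count was 69, with 1 lower.

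Fold changes from different probes of a gene were only loosely related. Across the 5877 genes with probes on different membranes, the Pearson correlation of log2 fold changes was 0.22 and the Spearman correlation 0.15, and 55.1% of pairs had the same sign. On the same membrane these were 0.18, 0.10 and 51.6% over 2263 genes. For the 33 genes whose brighter probe passed, the correlation between membranes was 0.48, 78.8% had the same sign, and in 11 the second probe went the same way at an unadjusted p under 0.05. These correlations are across genes, which are not independent replicates. Pairs between membranes were not restricted to different clones, so they can include repeat spots, such as those of Dld on MA08 and MA11. Pairs on the same membrane were of different clones. The figures between membranes and on the same membrane are therefore not directly comparable. Pairs of different clones between membranes were not examined separately.

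Duplicates of a split RNA differed nearly as much as different animals did on MA07, MA08 and MA11, and on MA10 the summer duplicates differed more than the median pair of summer animals, though less than summer animals 1 and 2 did. On MA07 the technical SD was 0.34 and 0.38 for the summer RNAs and 0.25 for the torpid RNA, against medians of 0.41 between summer and 0.31 between torpid animals. MA10 was noisier, with technical SDs of 0.91, 0.81 and 0.49 and animal SDs of 0.74 and 0.56. On MA08 and MA11 the technical SD was 0.42, 0.40 and 0.32, and 0.41, 0.41 and 0.36.

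**Figure D3:**
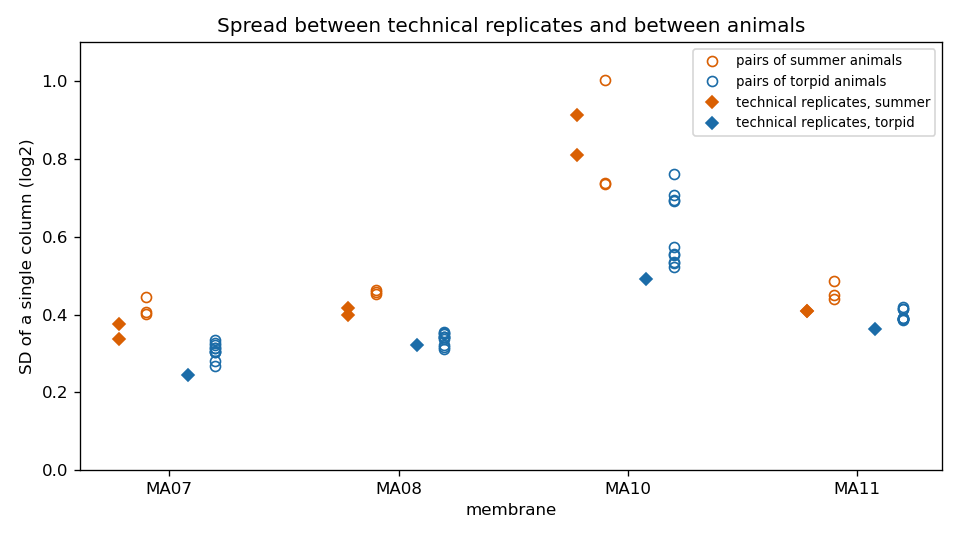
SD of a single column on the log2 scale for each membrane, from duplicates of a split RNA (filled diamonds) and from pairs of animals of 1 group (open circles), in orange for summer and blue for torpor. The summer duplicates lie above the torpid duplicates on all 4 membranes, for example 0.34 and 0.38 against 0.25 on MA07.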

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

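The outlying values below were found by a test chosen in advance, in which the gap between an extreme torpid animal and the nearest of the others is divided by the range of the 5 torpid animals. Values above 0.71 were singled out. Of 136 groups tested, 132 of named-gene probes and 4 of correlations between animals, 7 were above it, where chance gives about 6.8.

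Anapc7, the only called gene among them, had a ratio of 0.725 on MA07 (probe 4315), with torpid animal 4 at 1.39 against 2.21 to 2.52 in the others, on the side of the summer animals. Rpsa, a ribosomal protein gene, had 0.817 at MA10 probe 4469, with torpid animal 5 at 3.59 against 4.499 to 4.70. Torpid animal 1 stood apart for Pgd (pentose phosphate pathway, ratio 0.79, 2.84 against 1.67 to 1.92), Srebf2 (regulator of sterol synthesis, 0.772, -0.58 against 0.04 to 0.22) and H2-Eb1 (antigen presentation, 0.793, -1.39 against -0.32 to -0.04). Psma2, a proteasome subunit, had 0.756, with torpid animal 3 at 1.28 against 0.90 to 0.99. On MA08 the mean Spearman correlation of torpid animal 5 with the other torpid animals was 0.889 against 0.872 to 0.877, a ratio of 0.713, but only this animal was an average of 2 columns. With its first column alone its correlations with the others were 0.855 to 0.864, where the other pairs gave 0.859 to 0.878. No explanation of these values was tested.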

How the results depend on the processing

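Alternatives were fixed in advance, except a variance per group, the averaging of repeated spots and the removal of probes beside a brighter probe, of the bright group of MA11 or of MA10, which were chosen after seeing the data. Where a result changed, the cause was not tested unless the alternative itself removes probes or animals or moves the threshold. Of the named-gene values over these alternatives, 3241 kept direction and side of the threshold, 191 were no longer past it, 87 came to pass it and 43 changed sign, 27 of these Actb probes. None of the 23 most changed genes changed sign. These were chosen for complete separation of the groups, so leaving out an animal could not have reversed them. Sucla2, Acadm, Eef1g and Rps10 passed whichever animal was left out, while Rpl3 passed in none of these fits. The rise of the tricarboxylic acid cycle and respiratory chain lists passed under each alternative except an estimated correlation, while fry, which makes no comparison with other genes, gave 0.14 and 0.20. The rise of fatty acid oxidation passed under each except an estimated correlation and the probe of median fold change. A setting without a floor is the analysis as reported and was not run separately. Scanner files with background were not used, so no limit from signal over background could be set.

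Leaving out each of the 8 animals in turn gave 17 to 347 called probes, 13 to 253 higher and 4 to 94 lower, with 3 to 96 on MA07, 3 to 101 on MA08, 6 to 92 on MA10 and 5 to 58 on MA11. Members past the threshold ranged over 1 to 4 for fatty acid oxidation, 0 to 1 for triacylglycerol storage, 0 for cholesterol synthesis, 0 to 1 for glycolysis, 0 to 3 for the tricarboxylic acid cycle, 0 to 10 for the respiratory chain and 0 to 2 for ribosomal proteins. The other such ranges were 0 to 2 for translation factors, 0 to 2 for chaperones, 0 to 1 for the proteasome, 0 to 1 for extracellular matrix, 0 to 2 for antioxidants, 0 to 1 for immune markers and 0 to 1 for white adipocyte markers. Medians ranged over -0.10 to 0.085 for fatty acid synthesis, -0.031 to 0.14 for cholesterol synthesis, 0.24 to 0.43 for glycolysis, -0.56 to 0.043 for ribosomal proteins, 0.068 to 0.33 for the proteasome and 0.025 to 0.94 for cold-inducible proteins. For the remaining lists they ranged over -0.24 to 0.29 for antioxidants, -0.27 to 0.018 for cell division, -0.37 to 0.081 for muscle markers, -0.38 to 0.25 for erythroid markers, -0.089 to 0.12 for immune markers, -0.073 to 0.19 for endothelial markers and -0.60 to -0.039 for white adipocyte markers. Among named genes the sign changed for Hbb-b1 (-0.43 to 0.78) and Fasn (-0.24 to 0.069). It also changed for the Actb probes MA07 18 (-0.39 to 0.075), MA07 3611 (-0.84 to 1.16), MA07 4217 (-0.47 to 0.46) and MA07 4294 (-0.41 to 0.73). The further Actb probes with a change of sign were MA07 6749 (-0.63 to 0.048), MA07 7213 (-0.68 to 1.502), MA08 3081 (-0.74 to 1.38), MA08 3564 (-0.75 to 1.11) and MA08 8124 (-0.10 to 0.17). List calls were gained for cold-inducible proteins without summer animal 1 (adjusted p = 0.015) and summer animal 3 (adjusted p = 0.015), cell division without summer animal 2 (adjusted p = 0.012), torpid animal 2 (adjusted p = 0.041) and torpid animal 4 (adjusted p = 0.044) and the proteasome without summer animal 3 (adjusted p = 0.0019), torpid animal 2 (adjusted p = 0.044) and torpid animal 3 (adjusted p = 0.03). The list call of ribosomal proteins was lost without summer animal 3 (adjusted p = 0.84), that of glycolysis without summer animal 1 (0.12) or 2 (0.42), and that of white adipocyte markers without summer animal 3 (0.11). Without any 1 summer animal, 2 are left and their spread is pooled with that of the torpid animals.

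A list call was gained for the proteasome (median 0.22, adjusted p = 0.047) with median centring. Sign changes of list medians were seen for fatty acid synthesis (0.0021), cholesterol synthesis (-0.025) and immune markers (-0.00063). Quantile normalization left members past the threshold numbering 0 for cholesterol synthesis and ribosomal proteins. The call was gained for the proteasome (median 0.15, adjusted p = 0.036). Medians of opposite sign were seen for antioxidants (0.0072), immune markers (-0.019) and endothelial markers (-0.033). With quantile normalization gene values of opposite sign were Cry1 (0.097), Hbb-b1 (0.011) and Actb MA08 probe 3564 (-0.033). Cyclic loess gave 63 called probes, 46 higher, 9 on MA07, 8 on MA08 and 8 on MA11. The members past the threshold were then 0 for cholesterol synthesis, ribosomal proteins and chaperones and 1 for the tricarboxylic acid cycle and the respiratory chain. Changes of sign in medians were seen for cholesterol synthesis (-0.034), immune markers (-0.028), endothelial markers (-0.050) and nerve markers (-0.054). With cyclic loess gene values of opposite sign were Nefl (-0.061) and Actb MA07 probe 3611 (-0.49), MA07 probe 7213 (-0.43), MA08 probe 3081 (-0.15) and MA08 probe 3564 (-0.36). A floor at the 10th percentile gave 76 called probes, 64 higher, 12 lower, 10 on MA07 and 17 on MA08. List members past it then numbered 0 for cholesterol synthesis and the tricarboxylic acid cycle. The list test was lost for glycolysis (median 0.33, adjusted p = 0.057). Leaving out the dimmest 25% of probes gave 245 called probes, 194 higher, 51 lower, 46 on MA07, 59 on MA08, 86 on MA10 and 54 on MA11. Members that passed were then 3 for fatty acid oxidation, 1 for triacylglycerol storage, antioxidants and white adipocyte markers, 4 for the tricarboxylic acid cycle and 2 for ribosomal proteins. As a list, significance was gained for cell division (median -0.17, adjusted p = 0.045). Sign changes of list medians were seen for immune markers (-0.0030). Leaving out the dimmer 50% of probes gave 278 called probes, 219 higher, 59 lower, 58 on MA07, 57 on MA08, 98 on MA10 and 65 on MA11. Passing members numbered 3 for fatty acid oxidation, 1 for triacylglycerol storage, antioxidants and white adipocyte markers, 4 for the tricarboxylic acid cycle and 5 for the respiratory chain and ribosomal proteins. A list call was gained for the proteasome (median 0.40, adjusted p = 0.048). Medians of opposite sign were seen for fatty acid synthesis (0.046), antioxidants (0.079), immune markers (-0.022) and endothelial markers (-0.038). The correlation between probes of a gene was then 0.34.

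A variance trend with robust moderation gave 228 called probes, 177 higher, 51 lower, 39 on MA07, 63 on MA08, 77 on MA10 and 49 on MA11. The members past the threshold were then 2 for fatty acid oxidation and ribosomal proteins and 1 for antioxidants and white adipocyte markers. Weights per animal left members past the threshold numbering 1 for triacylglycerol storage and white adipocyte markers, 0 for cholesterol synthesis and the tricarboxylic acid cycle and 2 for ribosomal proteins. The call was gained for the proteasome (median 0.24, adjusted p = 0.025). Changes of sign in medians were seen for cholesterol synthesis (-0.023) and erythroid markers (0.018). With weights per animal gene values of opposite sign were Hbb-b1 (0.22) and Actb MA07 probe 3611 (-0.027), MA08 probe 3081 (-0.12) and MA08 probe 3564 (-0.31). Adjustment within each membrane gave called probes numbering 10 on MA07. List members past it then numbered 1 for white adipocyte markers. A threshold of 0.1 gave 304 called probes, 236 higher, 68 lower, 73 on MA07, 76 on MA08, 95 on MA10 and 60 on MA11. Members that passed were then 3 for fatty acid oxidation and ribosomal proteins, 1 for triacylglycerol storage, antioxidants and white adipocyte markers, 4 for the tricarboxylic acid cycle and 6 for the respiratory chain. The list test was gained for the proteasome (median 0.23, adjusted p = 0.051) and cell division (median -0.17, adjusted p = 0.055). Using only the first duplicate gave 176 called probes, 156 higher and 48 on MA07. Passing members numbered 2 for fatty acid oxidation, 1 for triacylglycerol storage and 0 for ribosomal proteins. As a list, significance was lost for white adipocyte markers (median -0.23, adjusted p = 0.062). Sign changes of list medians were seen for fatty acid synthesis (0.019) and immune markers (-0.15). With only the first duplicate gene values of opposite sign were Mag (-0.013), Actb MA07 probe 4294 (-0.0015), MA07 probe 6749 (0.028), MA08 probe 3081 (-0.11) and MA08 probe 3564 (-0.052) and Cirbp (-0.0076).

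Using only the second duplicate gave 38 called probes, 24 higher, 7 on MA07, 7 on MA08, 14 on MA10 and 10 on MA11. The members past the threshold were then 0 for cholesterol synthesis and ribosomal proteins and 1 for the respiratory chain and white adipocyte markers. A list call was lost for glycolysis (median 0.38, adjusted p = 0.16). The call was gained for cell division (median -0.20, adjusted p = 0.017). Medians of opposite sign were seen for cholesterol synthesis (-0.029), antioxidants (0.048) and endothelial markers (-0.061). With only the second duplicate gene values of opposite sign were Hbb-b1 (0.063), Actb MA07 probe 18 (0.052), MA07 probe 4217 (-0.016) and MA08 probe 8124 (-0.13) and Lpl (-0.12). All 11 columns with a duplicate correlation gave 285 called probes, 234 higher, 51 lower, 77 on MA07, 68 on MA08, 81 on MA10 and 59 on MA11. List members past it then numbered 4 for fatty acid oxidation, the tricarboxylic acid cycle and ribosomal proteins, 1 for glycolysis, the proteasome, antioxidants and white adipocyte markers and 8 for the respiratory chain. The list test was gained for the proteasome (median 0.25, adjusted p = 0.023). Changes of sign in medians were seen for cholesterol synthesis (-0.037), antioxidants (0.086) and immune markers (-0.0014). With all 11 columns with a duplicate correlation gene values of opposite sign were Hbb-b1 (0.25). The probe of median fold change left members past the threshold numbering 0 for fatty acid oxidation, cholesterol synthesis and chaperones. As a list, significance was lost for fatty acid oxidation (median 0.065, adjusted p = 0.077), glycolysis (median 0.12, adjusted p = 0.076) and white adipocyte markers (median -0.12, adjusted p = 0.68). Sign changes of list medians were seen for cholesterol synthesis (-0.081), chaperones (-0.042), the proteasome (-0.0088), the circadian clock (-0.00043), immune markers (-0.084) and nerve markers (-0.0047). A list call was lost for fatty acid oxidation (median 0.42, adjusted p = 0.099), glycolysis (median 0.33, adjusted p = 0.34), the tricarboxylic acid cycle (median 0.41, adjusted p = 0.34), the respiratory chain (median 0.30, adjusted p = 0.43), ribosomal proteins (median -0.29, adjusted p = 0.58) and white adipocyte markers (median -0.22, adjusted p = 0.34) with an estimated correlation.

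A replicate block gave 31 called probes, 24 higher, 7 lower, 5 on MA07, 5 on MA08, 16 on MA10 and 5 on MA11. Members that passed were then 0 for cholesterol synthesis, the respiratory chain and ribosomal proteins and 1 for the tricarboxylic acid cycle. The call was lost for glycolysis (median 0.39, adjusted p = 0.074). Medians of opposite sign were seen for immune markers (-0.0049), endothelial markers (-0.029) and nerve markers (-0.026). With a replicate block gene values of opposite sign were Mag (-0.042) and Scd1 (-0.14). This fit pairs summer and torpid animals of the same number, although the labels give different animals. The deviations of same-numbered animals from their group means correlated at -0.063 to 0.052 over 12 pairs (median 0.014, against -0.0012 for other pairs), so the numbers do not pair the animals.

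A variance per group gave 81 called probes, 67 higher and 14 lower, with 13 on MA07 and 18 on MA08. Passing members numbered 0 for cholesterol synthesis. Averaging repeated spots changed the sign of the medians of immune markers (-0.020). Leaving out probes beside a brighter probe gave called probes numbering 32 lower and 33 on MA07. The members past the threshold were then 2 for fatty acid oxidation and ribosomal proteins and 1 for white adipocyte markers. The list test was lost for glycolysis (median 0.26, adjusted p = 0.1). Changes of sign in medians were seen for fatty acid synthesis (0.020), antioxidants (0.041) and immune markers (-0.056). Leaving out the bright group of MA11 left members past the threshold numbering 0 for ribosomal proteins. Leaving out MA10 gave 69 called probes and 1 lower. List members past it then numbered 2 for fatty acid oxidation and 0 for cholesterol synthesis, ribosomal proteins and translation factors. As a list, significance was lost for white adipocyte markers (median -0.12, adjusted p = 0.48). A list call was gained for extracellular matrix (median -0.073, adjusted p = 0.042) and cell division (median -0.21, adjusted p = 0.037). Sign changes of list medians were seen for fatty acid synthesis (0.059), cholesterol synthesis (-0.042) and antioxidants (0.0045).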

Other observations

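Tests of the scatter among summer animals by their duplicates and by animal variance, of neighbouring probes on MA07, and of ribosomal probes without summer animal 3 were chosen only after the results were seen. So were the spread between animals among brighter probes, the division of the called genes by membrane, the genes named in the next paragraph and the examination of bright MA11 probes.

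Further genes with a probe that rose were picked for their products, and no test of them as a group was made. Hspa9, the mitochondrial Hsp70, passed with 3 of 7 probes (1.78, 2.61 and 2.38). The last 2 are of the same clone, which gave -0.62 and -0.41 on MA08. Cox6c passed with both of its probes (2.25 and 2.01). Atp5b, a catalytic subunit of ATP synthase, passed with 1 of 6 (2.29), Slc25a20, which brings acylcarnitines into mitochondria, with 1 of 3 (1.73) and Timm17a (protein import) with 1 of 3 (2.04), and no probe of these 3 genes was negative. Mmut (methylmalonyl-CoA mutase) passed with 1 of 3 (2.20, the others 1.23 and -0.43), the aspartate-glutamate carrier Slc25a12 with 1 of 3 (2.16, the others -0.10 and -0.08) and Marchf5, a ubiquitin ligase of the outer mitochondrial membrane, with 1 of 2 (2.47, the other 0.10). Outside mitochondria, Atp1b1, a sodium pump subunit, passed with 1 of 5 probes (2.58, the lowest -0.91), the small heat shock protein gene Cryab with 1 of 5 (1.6, the lowest 0.22) and Adcy3, an adenylate cyclase, with 1 of 2 (1.68, the other 1.75).

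The 8 animals can be divided into groups of 3 and 5 in 56 ways. Only the real division (1 of 56) gave as many as 117 called probes, and the highest other gave 1. The same held for the 98 higher (highest other 1) and 19 lower (0) and for the 20, 33, 38 and 26 called on MA07, MA08, MA10 and MA11 (0, 0, 1 and 0). A share of 1 in 56 is the smallest that these divisions can give, so chance is made less likely for these counts but is not excluded. For fatty acid oxidation 1 of the 56, the real division, gave a camera p as small as the real 7.1e-07 (smallest other 0.00021). Chance is not excluded there, since only lists that had already passed were tested in this way. That list call was also lost with an estimated correlation (0.099) and with each gene's probe of median fold change (0.077). For white adipocyte markers 2 divisions gave a camera p as small (real 0.0027, smallest other 0.00091), a share under 0.05, although the division of torpid animals 1, 2 and 3 from the rest gave the smaller p. The white adipocyte call was lost with an estimated correlation (0.34), without summer animal 3 (0.11) and without MA10 (0.48). A share above 0.05 gave a camera p as small for the tricarboxylic acid cycle (3 divisions, real 1.8e-07, smallest other 1.4e-10) and glycolysis (5, real 0.0036, smallest other 0.00060). The same held for the respiratory chain (11, real 3.3e-06, smallest other 3.0e-16) and ribosomal proteins (23, real 1.5e-06, smallest other 5.6e-15). Chance is not excluded for these lists either.

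Summer animals scattered more than torpid animals on all 4 membranes, by the median over pairs of animals. Noise of dim probes alone is argued against: among the brighter 50% of probes every pair of summer animals differed more than every pair of torpid animals on MA07 (at least 0.413 against at most 0.301), MA08 (0.421 and 0.312) and MA11 (0.415 and 0.385), though not on MA10 (0.705 and 0.735), and summer duplicates differed more than torpid duplicates in 8 of 8 comparisons there. Noisier summer hybridisations and greater differences between the summer animals themselves cannot be told apart. Summer duplicates differed more in 8 of 8 comparisons among all probes, but each of these is against the same single torpid RNA, and the between-animal variance less the technical variance was larger in summer on 3 of 4 membranes. Differences between seasons in the animals stay open as well.

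Probes 5 index positions apart on MA07 moved together, among them Cycs (3.24) and Fndc3a (2.77). Probes for the same gene are argued against, since pairs with different gene names kept an excess correlation of 0.18. Bleed of signal from bright neighbouring spots may explain this, since the median signal percentile of probes 5 positions from the brightest 1% was 31.4 points above that at 3, 4, 6 and 7 positions, but which probe numbers are neighbours on the membrane is not given in the sources used here. For the same reason a gradient across the membrane stays open: the correlation at 4 and 6 positions was 0.19 of that at 5, while at 600 positions the correlation was 0.16, and 0.11 and 0.12 at 5 positions fewer and more. On MA08 the called pairs 5 positions apart were Sucla2 (4.30) with Ppp4c (1.95) and an unnamed probe (2.98) with Zyg11b (2.12), and no biological explanation was tested. The correlation at 10 positions was 0.11 on MA07, 0.067 on MA08, 0.15 on MA10 and 0.15 on MA11, and 3 of the 4 called Eef1g probes lie 10 positions apart on MA10 (-2.83, -2.89 and -2.78), so they may not be separate support.

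The called ribosomal protein probes lay on MA10, where 87 of 93 were lower and 7 were called, with a median of -0.85. On MA07, MA08 and MA11, 50 of 88, 26 of 49 and 11 of 17 were lower, and 0 were called. Of the 7 genes with a called probe, Rps10 and Rpl3 had probes on 2 membranes, with highest values of -1.36 and -1.08. Rps15, Rpsa and Rplp1 had probes on 4, 3 and 3 membranes, with highest values of -0.33, -0.47 and -0.08. Rpl36 and Rpl35 had probes on MA10 alone. A brightness-dependent shift is argued against by 684 probes of other genes matched on signal (median 0.066), and torpid animal 1 or summer animal 3 alone by medians of -0.87 and -0.79 without them. Smaller fold changes of all probes on the other membranes stay open: the median absolute log2 fold change on MA10 was 0.87 times that elsewhere over 35 called genes, but 33.9 times over the 9 called only on MA10 and 0.498 times over the 24 called only elsewhere, so the choice of genes decides this ratio, and the spread of all log2 fold changes was 0.56 on MA10 against 0.32, 0.35 and 0.41. Ribosomal levels of summer animal 3 were above those of summer animals 1 and 2 on MA07, MA08 and MA11 (2.81, 3.10 and 4.23 against at most 1.52, 1.97 and 2.49), but not on MA10 (3.40 against 3.62 in summer animal 1). Cross-hybridisation between related sequences was not tested, and a difference between torpor and summer stays open.

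MA11 held 198 probes brighter than 32 times the column median, for 111 genes, against 28, 36 and 130 such probes on MA07, MA08 and MA10. Of these, 176 were lower in torpor, with a median of -0.56 and a spread of 0.28, where the next brightest 198 had a median of 0.56 and a spread of 1.02, and 1 was called. Their probe numbers ended in 1, 3 or 7 in 60.6% of cases, against 30.1% of all MA11 probes. Probes for the same genes on the other membranes had a median of -0.0091. Among them were Bub1 (-0.71), Cry1 (-0.47), Tnnc2 (-0.77) and Lama1 (-0.93).

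Of the probes with empty cells, 2 were empty in all summer and no torpid animals, and 6 in all torpid and no summer animals, 5 of them on MA10.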
